A study of Drosophila melanogaster with 10 samples.

How the data were processed

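Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out by the authors on Kc167 cells, an established cell line derived from Drosophila melanogaster embryos, grown at 25 °C. The series holds 10 libraries, of which 8 are ChIP libraries and 2 are input libraries. Mod(mdg4)2.2, Rump and Shep were each precipitated with 2 antibodies, and Su(Hw) and CP190 with 1 antibody each. Per the labels, every ChIP library except that of CP190 came from the first of 2 chromatin preparations and was paired with that preparation's input, while the CP190 library came from the second preparation with its own input. CP190 is therefore the only list from the second preparation, and preparation cannot be separated from factor for it.

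The authors deposited 1 peak list per factor, so the 2 antibodies of Mod(mdg4)2.2, Rump and Shep are already combined and no value per library was available here. Per the submitters' processing notes, reads were handled with Trimmomatic 0.20, cutadapt 1.1, Bowtie 0.12.8, bedtools 2.17.0 and Picard 1.77, with genome build dm3. The peak caller, its threshold, the way in which 2 libraries were combined, the treatment of reads mapping to several places and the number of reads per library are not given in the sources used here. The lists of Mod(mdg4)2.2, Rump and Shep follow the narrowPeak layout. The seventh column of these lists, as deposited, holds a signal value for each peak, called the peak score below. It is the authors' own score and was used to rank, stratify and compare peaks within a list. Between lists it was used only to correlate Rump and Mod(mdg4)2.2 scores at shared peaks. The ninth column holds, by that layout, the −log10 of a q-value, as deposited by the authors. All peaks of a list have the same width in these 3 lists. The deposited lists of Su(Hw) and CP190 hold only the start and end of each peak and have no score. Start positions, counted from 0 in the files the authors deposited, are given here counted from 1.

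Peaks of a pair of lists counted as shared when they overlapped by at least 1 bp. For each of the 10 pairs of lists, the smaller list was rotated along each chromosome by a random offset, 100000 times, and the number of its peaks meeting the larger list was recounted. Such a rotation keeps the number, the width and the spacing of the peaks and breaks their position relative to the other list. The p-values of this permutation test are two-sided, and 2e-05 is the smallest that it can give. Chromosome lengths were taken as the highest peak end over the 5 lists. Shares carry Wilson 95% intervals, which cover counting error only, since the spread between antibodies, libraries or cultures cannot be seen in 1 list per factor. An interval of a fold is that of the share divided by the mean of the rotations. Lists differ in peak width, and a wide list is met more often by chance, so that folds over rotation are compared between lists only after all peaks were resized to 300 bp. Whether Rump went with a second factor within the peaks of another was tested with Fisher's exact test, two-sided, over 12 such comparisons. Where a count of 0 left an odds ratio without a finite value, 0.5 was added to each of its 4 counts. For combinations, all peaks that overlapped by at least 1 bp were merged into regions. Medians of score or width were compared with a permutation test, two-sided, of 100000 resamples, of which 1e-05 is the smallest p. Each family of tests was adjusted by Benjamini-Hochberg, with a threshold of 0.05. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, Numba 0.67.0 and matplotlib 3.10.9 were used.

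The overlap test was tested on simulated data made from the Rump and Mod(mdg4)2.2 lists. Among 200 randomly placed lists of 338 peaks, 3.5% gave a p under 0.05. Each simulated peak was placed evenly along its chromosome and independently of the others. The simulation therefore does not cover clustered peaks, or lists that share regions where many factors bind. With 7 shared peaks planted, 82% of 50 simulated lists did so, and with 17 planted all did. The test of medians gave a p under 0.05 in 3.5% of 200 random splits of the 2678 Mod(mdg4)2.2 scores and in 83.5% when the scores of 1 side were raised by 25%.

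The regions named were chosen by a rule fixed before the data were examined: the 3 peaks of highest score in each list (the widest where there is no score), up to 10 regions with all 5 factors and up to 10 with Rump alone, ranked by Rump score, and the 3 windows of 100 kb with the most Rump peaks. Alternatives fixed at the same time were other overlap rules, the top 50% of each list (by width for Su(Hw) and CP190), lists of equal size, another model of chance, other sets of chromosomes and another merging distance. Alternatives that used q, peak width or strata of Mod(mdg4)2.2 score were added after the data had been seen. No genome or annotation of build dm3 was used here, and the gene table at hand is of Release 6. Positions were not converted between builds, so regions are given by coordinate without gene names, and the planned comparisons of promoters, gene lists and sequence motifs were not made. The −log10 q was used only for such filters.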

Results

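The genomic positions of 5 proteins were mapped by ChIP-seq in Kc167 cells, a Drosophila line derived from embryos with features of blood cells. Su(Hw), a zinc-finger protein that binds DNA, Mod(mdg4)2.2 and CP190, both proteins with a BTB domain, form the core of the gypsy chromatin insulator. Rump (Rumpelstiltskin) is an RNA-binding protein of the hnRNP M family, and Shep (Alan shepard) is an RNA-binding protein known to act on the same insulator. The lists hold 338 peaks for Rump, 2678 for Mod(mdg4)2.2, 1443 for Shep, 2369 for Su(Hw) and 2742 for CP190. Rump, Mod(mdg4)2.2 and Shep peaks have fixed widths of 256, 304 and 484 bp. Su(Hw) and CP190 peaks are wider, with medians of 2106 and 2025 bp. The Rump, Mod(mdg4)2.2 and Shep lists each combine 2 libraries, and the Su(Hw) and CP190 lists come from 1 library each. Rump peaks have a q of at most 0.00509 and Mod(mdg4)2.2 peaks of at most 0.00624, whereas 454 of the 1443 Shep peaks have a q above 0.05, up to 0.156. The number of reads per library is unknown here, and there was no replicate of any list, so that every test below compares lists and not independent cultures.

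The first comparison asked where on the chromosomes Rump lies relative to the insulator proteins and to Shep. Most Rump peaks lay at insulator protein sites. Of the 338 Rump peaks, 276 (81.7%, 95% interval 77.2 to 85.4) overlapped a Mod(mdg4)2.2 peak, 267 (79.0%, 74.3 to 83.0) a Su(Hw) peak and 247 (73.1%, 68.1 to 77.5) a CP190 peak. Only 22 (6.51%, 4.34 to 9.66) overlapped a Shep peak. Mod(mdg4)2.2, Su(Hw) and CP190 together were present at 234 Rump peaks (69.2%, 64.1 to 73.9), and 47 Rump peaks (13.9%, 10.6 to 18.0) met none of the other lists. The median distance from the midpoint of a Rump peak to the nearest midpoint was 22 bp for Mod(mdg4)2.2, 59 bp for CP190, 106.5 bp for Su(Hw) and 25736 bp for Shep, over the 335, 332, 337 and 302 Rump peaks on chromosomes or scaffolds where that factor had a peak. Seen from the larger lists, Rump was present at 10.5% of Mod(mdg4)2.2 peaks, 11.1% of Su(Hw) peaks, 8.86% of CP190 peaks and 1.52% of Shep peaks.

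Of the 338 peaks of a rotated Rump list, 3.66 ± 2.01 (mean and SD over rotations) met the Mod(mdg4)2.2 list, 14.9 ± 3.90 the Su(Hw) list, 14.9 ± 3.94 the CP190 list and 2.59 ± 1.59 the Shep list. The observed overlap was thus 75.4-fold (71.2 to 78.8) that of the rotations for Mod(mdg4)2.2, 17.9-fold (16.8 to 18.8) for Su(Hw), 16.6-fold (15.5 to 17.6) for CP190 and 8.49-fold (5.66 to 12.6) for Shep. Each of these had an adjusted p of 2e-05 by the permutation test, the smallest that the rotations can give. With all peaks resized to 300 bp, a setting chosen after the widths had been seen, the excess was 70.9-fold for Mod(mdg4)2.2, 62.3-fold for Su(Hw), 55.7-fold for CP190 and 9.96-fold for Shep. With Shep peaks of q up to 0.05, the overlap with Shep was 10 peaks (5.57-fold), and with q up to 0.01 it was 6 peaks (5.35-fold). It was not past the threshold in the top 50% of each list, where 1 of 169 Rump peaks met Shep (1.58-fold, adjusted p = 0.947, permutation test), or with lists of equal size (3.23-fold, adjusted p = 0.278). Among regions holding a peak of at least one of the other 3 factors, Rump and Shep were not associated (odds ratio 0.937, adjusted p = 0.785, Fisher's exact test), while Rump and Mod(mdg4)2.2 were (odds ratio 40.1, adjusted p = 1e-86).

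**Figure D1:**
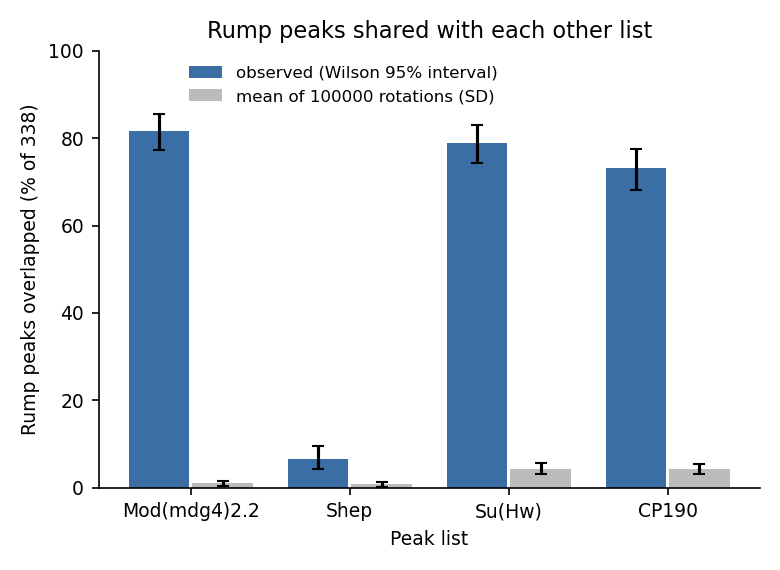
Bars give the percentage of the 338 Rump peaks that overlapped a peak of each other list (blue, with Wilson 95% intervals) and the mean percentage over 100000 rotations of the Rump list (grey, with the SD over rotations). Mod(mdg4)2.2, Su(Hw) and CP190 met 81.7%, 79.0% and 73.1% of Rump peaks, and Shep met 6.51%.

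The other 4 lists were compared in the same way. The insulator proteins overlapped one another widely. Su(Hw) peaks carried Mod(mdg4)2.2 at 1597 of 2369 sites (67.4%, 65.5 to 69.3) and CP190 at 1166 sites (49.2%, 47.2 to 51.2), and Mod(mdg4)2.2 peaks carried CP190 at 1609 of 2678 sites (60.1%, 58.2 to 61.9). These overlaps were 13.2-fold, 5.34-fold and 11.7-fold those of the rotations, each with an adjusted p of 2e-05 by the permutation test. With peaks resized to 300 bp they were 44.4-fold, 29.6-fold and 36.4-fold. Shep stood further apart. Of 1443 Shep peaks, 835 (57.9%, 55.3 to 60.4) met no other list, against 11.2% of Mod(mdg4)2.2, 26.0% of Su(Hw) and 36.6% of CP190 peaks. These shares are of lists of unlike peak width, and 454 Shep peaks have a q above 0.05. The overlap with Mod(mdg4)2.2 was also lower at lower Shep scores. Mod(mdg4)2.2 was at 42.1% of Shep peaks in the highest score decile and 8.33% in the lowest. Su(Hw) and CP190 showed no such steady fall. Su(Hw) was at 15.2% and 6.25% in the same deciles, but its highest share, 16.7%, was in decile 5 from the highest score. CP190 was at 26.9% and 20.1%, and its highest share, 35.2%, was in decile 7. Shep met CP190 at 375 peaks (26.0%, 23.8 to 28.3, 4.66-fold), Mod(mdg4)2.2 at 292 (20.2%, 18.2 to 22.4, 11.7-fold) and Su(Hw) at 184 (12.8%, 11.1 to 14.6, 2.42-fold), again with adjusted p = 2e-05 by the permutation test. Resized to 300 bp, these were 10.8-fold for CP190, 14.2-fold for Mod(mdg4)2.2 and 4.41-fold for Su(Hw). The overlap of Shep and Mod(mdg4)2.2 did not pass with lists of equal size (1.32-fold). Those folds have the whole chromosome as background. Among regions bound by another factor, the association of Shep with Su(Hw) was negative (odds ratio 0.373, adjusted p = 1e-22, Fisher's exact test), and those of Shep with Mod(mdg4)2.2 and with CP190 did not pass the threshold (odds ratios 0.812 and 0.871, adjusted p = 0.0521 and 0.233).

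Merging all peaks gave 5224 regions. CP190 alone was the most frequent combination, with 1003 regions, followed by Shep alone with 812 and by Mod(mdg4)2.2, Su(Hw) and CP190 together, without Rump or Shep, with 765. Rump was present in 333 regions, of which 207 held Mod(mdg4)2.2, Su(Hw) and CP190 without Shep, 25 held all 5 factors, 21 held Mod(mdg4)2.2 and Su(Hw) only besides Rump, and 47 held Rump alone. A merged region can join peaks that do not overlap one another. Counted per peak, 14 Rump peaks overlapped all 4 other lists directly. A single region held Rump and Shep without any insulator protein.

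**Figure D2:**
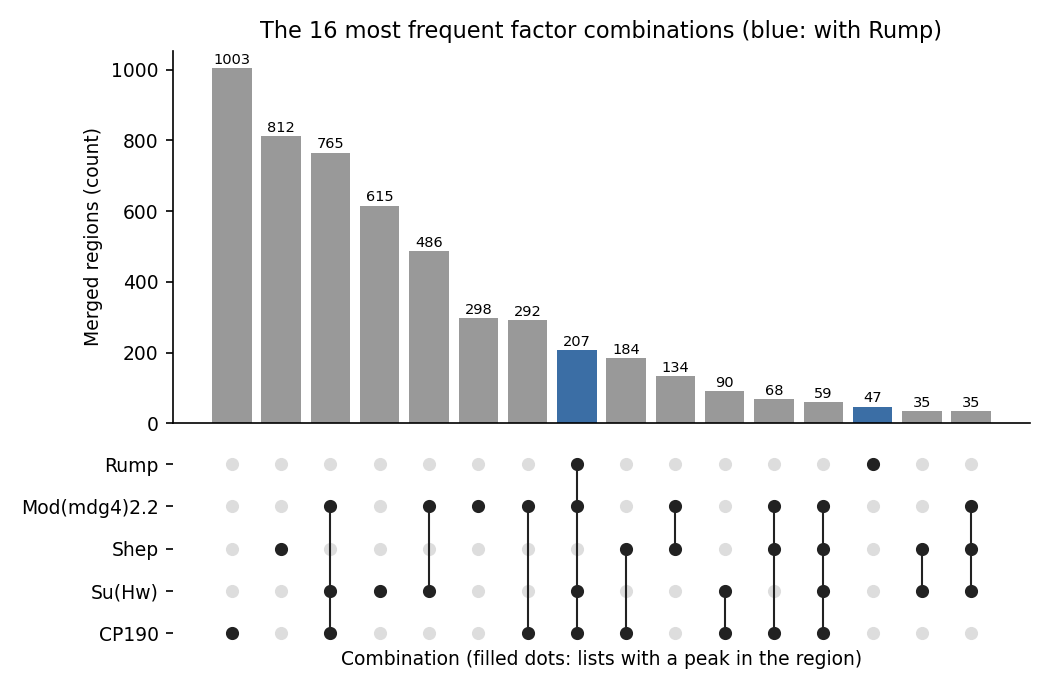
Bars count the merged regions with each of the 16 most frequent combinations of factors, and the dots under each bar show which lists have a peak in the region. The most frequent combination with Rump (blue) is Rump with Mod(mdg4)2.2, Su(Hw) and CP190, with 207 regions, and Rump alone has 47.

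The next comparison asked whether Rump and Shep prefer the complete insulator combination. The shares of Rump and Shep went in opposite directions. Of the 1056 regions with Su(Hw), Mod(mdg4)2.2 and CP190, 232 (22.0%, 19.6 to 24.6) held Rump, against 44 of the 1357 regions (3.24%, 2.42 to 4.32) with Mod(mdg4)2.2 that lacked Su(Hw) or CP190 (odds ratio 8.40, adjusted p = 3e-48, Fisher's exact test). Shep was present in 84 of the complete regions (7.95%, 6.47 to 9.74) and in 245 of the others (18.1%, 16.1 to 20.2), with an odds ratio of 0.392 and an adjusted p of 2.7e-13. Within deciles of Mod(mdg4)2.2 score, a setting chosen after the data had been seen, and counted per Mod(mdg4)2.2 peak, the odds ratio was 1.86 for Rump (1.17 to 2.94) and 0.417 for Shep (0.296 to 0.588). Neither call passed the threshold with lists of equal size, in which 31 complete regions remained. There the odds ratio was 1.68 for Rump, and that for Shep turned to 4.98, from 1 complete region with Shep. The call for Shep did not pass in the top 50% of each list either (odds ratio 0.721, adjusted p = 0.247, Fisher's exact test).

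Pairs of factors were then held fixed to see with which partner Rump goes. Within CP190 peaks, Rump was present at 240 of 1431 sites with Mod(mdg4)2.2 (16.8%, 14.9 to 18.8) and at 3 of 1311 sites without it (0.229%, 0.0779 to 0.671), an odds ratio of 87.9 (adjusted p = 1e-66, Fisher's exact test). Within Su(Hw) peaks, it was present at 257 of 1597 sites with Mod(mdg4)2.2 (16.1%) and at 6 of 772 sites without it (0.777%, odds ratio 24.5, adjusted p = 3.3e-38, Fisher's exact test). Within CP190 peaks, Rump also went with Su(Hw), at 19.5% of 1183 sites with Su(Hw) and 0.770% of 1559 sites without it (odds ratio 31.3, adjusted p = 9.3e-73, Fisher's exact test). Within Su(Hw) peaks, Rump went with CP190, at 19.9% of 1166 sites with CP190 and 2.58% of 1203 sites without it (odds ratio 9.39, adjusted p = 1.4e-44, Fisher's exact test). Mod(mdg4)2.2 was left free in both comparisons. Among merged regions without it, 90 held Su(Hw) and CP190 only and 15 held these with Shep. No region held Rump, Su(Hw) and CP190 without Mod(mdg4)2.2, so a difference by either partner was not seen apart from Mod(mdg4)2.2. Over the alternatives, the odds ratio within CP190 peaks ran from 66.4 to 435 by Mod(mdg4)2.2 and from 3.34 to 45.8 by Su(Hw), which fell to 14.6 with peaks resized to 300 bp, and within Su(Hw) peaks from 17.6 to 149 by Mod(mdg4)2.2. The 435 and the 149 are not finite estimates, since no site without Mod(mdg4)2.2 held Rump there and 0.5 was added to each count. Within Mod(mdg4)2.2 peaks, Rump was present at 14.3% of sites with Su(Hw) and 2.24% of sites without it (odds ratio 7.27, adjusted p = 1.3e-25), and at 15.4% of sites with CP190 and 3.09% of sites without it (odds ratio 5.69, adjusted p = 2.7e-27, each by Fisher's exact test). Within deciles of Mod(mdg4)2.2 score, the odds ratio for CP190 was 1.90 (adjusted p = 0.0271, Mantel-Haenszel test, n = 2678 peaks), and that for Su(Hw) was 0.591 (adjusted p = 0.124). The value for Su(Hw) has little contrast behind it. Su(Hw) was at 263 of 268 peaks in the highest decile and 262 of 268 in the second, where most peaks with Rump lay (195 and 51). With lists of equal size, neither the call for CP190 nor that for Su(Hw) passed the threshold (odds ratios 1.89 and 1.1).

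Most of the 22 Rump sites in the Shep list were also insulator sites, as were Rump peaks in general. Of all 338 Rump peaks, 81.7% overlapped Mod(mdg4)2.2, 79.0% Su(Hw) and 73.1% CP190. The odds ratios within Shep peaks thus need not be particular to Shep. Rump was present at 18 of 292 Shep peaks with Mod(mdg4)2.2 (6.16%, 3.93 to 9.53) and at 4 of 1151 without it (0.348%, 0.135 to 0.890), an odds ratio of 18.8 (adjusted p = 1e-09, Fisher's exact test). This was not past the threshold in the top 50% of each list (odds ratio 45.6, with 0.5 added to each count), where 1 Shep peak with Mod(mdg4)2.2 and none without it held Rump. Within Shep peaks, the odds ratio of Rump was 19.9 by Su(Hw) (adjusted p = 1.7e-10) and 10.1 by CP190 (adjusted p = 7.8e-07, each by Fisher's exact test). The calls by Su(Hw) and by CP190 passed the threshold neither in the top 50% nor with lists of equal size. Shep as the second factor gave no constant direction. Rump was less frequent at Mod(mdg4)2.2 peaks with Shep (6.23%) than without it (10.97%, odds ratio 0.539, adjusted p = 0.0130), more frequent at Su(Hw) peaks with Shep (16.7% against 10.7%, odds ratio 1.68, adjusted p = 0.0252), and not different at CP190 peaks (7.25% against 9.09%, odds ratio 0.781, adjusted p = 0.310, all by Fisher's exact test). The first of these turned over within deciles of Mod(mdg4)2.2 score, to an odds ratio of 2.07 (1.04 to 4.10, adjusted p = 0.0416, Mantel-Haenszel test, n = 2678 peaks), but was 1.13 (0.473 to 2.68) within those deciles with Shep peaks of q up to 0.05. Without deciles it was lower with that filter (0.312) and with q up to 0.01 (0.232), and it was lost without chromosome 2R, 3L or 3R (0.561, 0.603 and 0.615). The second was lost with Shep peaks of q up to 0.05 (odds ratio 1.57) and without chromosome 2L, 2R or X (1.51, 1.51 and 1.56), but not with peaks of q up to 0.01 (1.88, adjusted p = 0.0371, Fisher's exact test).

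Peak scores were compared to see at which Mod(mdg4)2.2 sites Rump lies. Rump lay mainly on the Mod(mdg4)2.2 peaks of highest score. The median score of Mod(mdg4)2.2 peaks with Rump was 335 (quartiles 279 and 388, 280 peaks), against 89.3 (quartiles 60.4 and 158, 2398 peaks) without Rump, a ratio of 3.75 (adjusted p = 2.7e-05, permutation test). In the decile of highest Mod(mdg4)2.2 score, 195 of 268 peaks had Rump (72.8%, 67.1 to 77.7). The share was 19.0% (14.8 to 24.2) in the second decile, 3.73% (2.04 to 6.73) in the third and 0.375% (0.0661 to 2.09) in the lowest. Of the 338 Mod(mdg4)2.2 peaks of highest score, 216 had Rump (63.9%, 58.7 to 68.8). Shep took the opposite course over the same deciles, at 3.73% (2.04 to 6.73) of the highest and 18.0% (13.8 to 23.0) of the lowest. Mod(mdg4)2.2 peaks with Shep had a median score of 72.2 against 108 without (ratio 0.669, adjusted p = 3e-05, permutation test, a comparison chosen after the deciles had been seen).

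**Figure D3:**
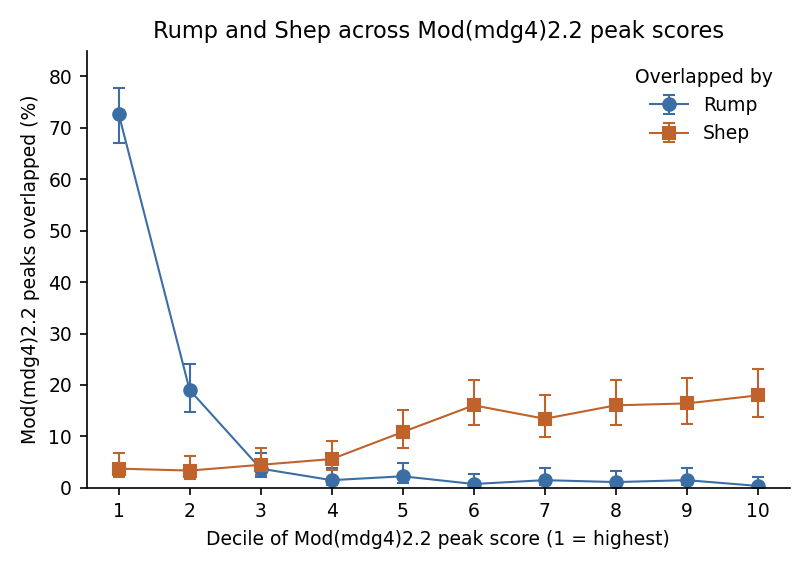
Points give the percentage of Mod(mdg4)2.2 peaks overlapped by a Rump peak (blue circles) or a Shep peak (orange squares) in each decile of Mod(mdg4)2.2 peak score, decile 1 being the highest, with Wilson 95% intervals. Rump was present at 72.8% of the peaks of the first decile and 0.375% of the last, and Shep at 3.73% and 18.0%.

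Su(Hw) and CP190 peaks with Rump were wider than those without it, with median widths of 2293 against 2083 bp for Su(Hw) and 2105 against 2017 bp for CP190 (each adjusted p = 2.7e-05, permutation test). A wider peak is also more likely to meet a Rump peak by its width alone, and the test makes no allowance for this. Within the Rump list, peaks with Mod(mdg4)2.2 had a median score of 25.3 against 21.3 without it (adjusted p = 0.0261, permutation test), and peaks with CP190 25.1 against 22.0 (adjusted p = 0.0337). Neither of these passed the threshold on 2L, 2R, 3L, 3R and X alone (adjusted p = 0.0801 and 0.0523, permutation test). The differences by Su(Hw) (25.0 against 22.0, adjusted p = 0.0527) and by Shep (20.3 against 24.9, adjusted p = 0.0756, permutation test) did not pass the threshold. Shep peaks with Rump had a median score of 93.0 against 108 without it, which was not past the threshold either (adjusted p = 0.0833, permutation test). Over the 276 Rump peaks with Mod(mdg4)2.2, the 2 scores had a Spearman rho of 0.41 (permutation p = 1e-04, the smallest that the permutations can give) and a Pearson r of 0.16 (permutation p = 0.0102), across peaks, which are not independent replicates.

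The distribution over chromosomes was compared last. Rump peaks were on X in 15.4% of cases (11.9 to 19.6), against 19.4% for Mod(mdg4)2.2, 17.4% for Shep, 19.97% for Su(Hw) and 20.6% for CP190, and none of these differences passed the threshold (lowest adjusted p = 0.189, Fisher's exact test). A single Rump peak was on chromosome 4, and none of the 4 comparisons on that chromosome passed the threshold. Outside the assembled arms, that is on the heterochromatic scaffolds (Het), the unplaced sequence (U) and the mitochondrial genome (M) of dm3, lay 45 of the 338 Rump peaks (13.3%, 10.1 to 17.4). The share was 0.822% for Mod(mdg4)2.2, 0.347% for Shep, 1.56% for Su(Hw) and 0.182% for CP190. Each differed from that of Rump (highest adjusted p = 6.1e-21, Fisher's exact test), a comparison chosen after the positions had been seen. U alone held 34 Rump peaks, against 9 of Mod(mdg4)2.2, 13 of Su(Hw), 2 of CP190 and 0 of Shep. Of the 45 Rump peaks outside the arms, 8 (17.8%, 9.29 to 31.3) overlapped Mod(mdg4)2.2, 8 Su(Hw), 1 CP190 and 0 Shep, and 31 (68.9%, 54.3 to 80.5) met no other list. On the arms, 268 of 293 Rump peaks (91.5%, 87.7 to 94.2) overlapped Mod(mdg4)2.2, 88.4% Su(Hw), 84.0% CP190 and 7.51% Shep, and 16 (5.46%, 3.39 to 8.69) met no other list.

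**Figure D4:**
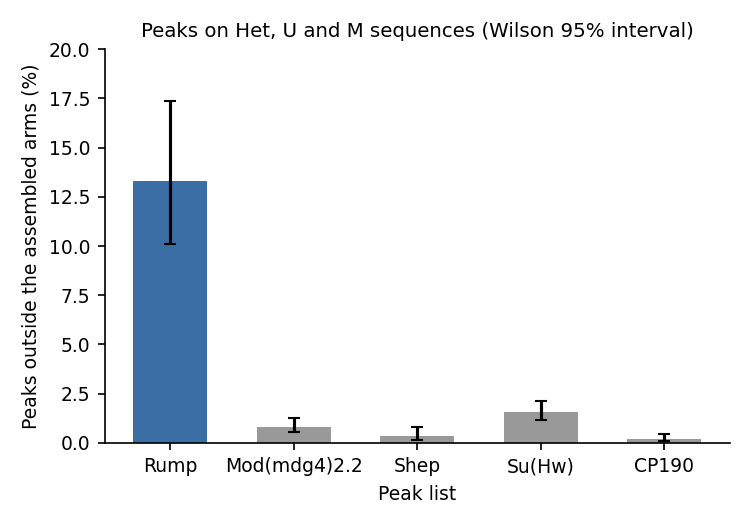
Bars give the percentage of each list's peaks on Het, U and M sequences of dm3, outside the assembled arms, with Wilson 95% intervals. Rump had 13.3% of its peaks there, and the other 4 lists between 0.182% and 1.56%.

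Regions are named by their dm3 coordinates, and genes or other features at these places were not analysed here. The Rump peak of highest score (190) lay on 3R from 19157085 to 19157340, at a site with Mod(mdg4)2.2, Su(Hw) and CP190. The next were on U, from 9795761 to 9796016 (score 120, with Mod(mdg4)2.2 and CP190) and from 9151155 to 9151410 (score 90.1, with Mod(mdg4)2.2 and Su(Hw)). The 3 Mod(mdg4)2.2 peaks of highest score were on 3R from 3807143 to 3807446 (score 544), on X from 18922669 to 18922972 (score 537) and on X from 20631343 to 20631646 (score 489). All 3 held Rump, Su(Hw) and CP190. None of the 3 highest Shep peaks held Rump. They were on 2R from 16161714 to 16162197 (score 315, with CP190), on 3R from 133447 to 133930 (score 265, with Mod(mdg4)2.2 and Su(Hw)) and on X from 18528656 to 18529139 (score 253, with Mod(mdg4)2.2 and CP190). The widest Su(Hw) peak spanned 7017 bp on 2R from 1972580 to 1979596, with Mod(mdg4)2.2 and CP190. The next covered 3R from 793491 to 800357, with Mod(mdg4)2.2, Shep and CP190, and 3L from 8929040 to 8935723, with no other factor. The widest CP190 peak spanned 5492 bp on X from 549088 to 554579, with Mod(mdg4)2.2 and Su(Hw). The next covered X from 1179298 to 1184128, with Rump, Mod(mdg4)2.2 and Su(Hw), and 2R from 12494072 to 12498898, with Mod(mdg4)2.2 and Su(Hw).

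Among the 25 regions with all 5 factors, the highest Rump score (64.3) was on 2L from 489094 to 491337. It was followed by regions on X from 15998005 to 16001103 (Rump score 41.6), on 2L from 14705291 to 14707664 (41.4), on 3L from 20532464 to 20536101 (39.9) and on 2R from 7059758 to 7061968 (34.8). The other 5 of the 10 with the highest Rump score were on 2R at 20179946, 12576051 and 16964166, on 2L at 6365970 and on 2R at 13279205, by their start, with Rump scores between 25.0 and 33.7. The regions with Rump alone of highest score were mostly outside the arms. The first was on U from 9598994 to 9599249 (Rump score 74.1), followed by 2LHet from 367878 to 368133 (50.8), U from 9934634 to 9934889 (46.6), 3LHet from 2163609 to 2163864 (44.8) and U from 8438471 to 8438726 (41.6). The next 5 were on 2RHet at 29, on 3L at 24168594, on U at 8333915, on 3L at 24167937 and on X at 1474752, by their start, with Rump scores between 29.6 and 36.6. No window of 100 kb held more than 3 Rump peaks, and 5 windows held 3. The first of these in chromosome order covered 2L from 400001 to 500000, with 10 Shep, 8 CP190, 6 Mod(mdg4)2.2 and 3 Su(Hw) peaks. The second covered 2R from 12500001 to 12600000, with 6 Mod(mdg4)2.2, 6 Su(Hw), 5 CP190 and 1 Shep peaks. The third covered 3L from 24100001 to 24200000, with 1 Mod(mdg4)2.2 peak and no peak of the other 3 factors.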

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

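The alternatives on q, on peaks resized to 300 bp and on strata of Mod(mdg4)2.2 score were chosen after the data had been seen, and the others before. Of 160 alternative values for the 10 pairwise overlaps, 153 kept their direction and their side of the threshold. The overlaps of Rump with Mod(mdg4)2.2 (17.9-fold to 463-fold over chance), Su(Hw) (10.2-fold to 62.3-fold) and CP190 (8.95-fold to 55.7-fold) did so under every alternative model of chance, overlap rule, filter and chromosome set run. The changes concerned Shep. Among regions bound by another factor, the odds ratios fell to the other side of 1 for Shep with Mod(mdg4)2.2 (0.812), Rump (0.937), CP190 (0.871) and Su(Hw) (0.373); this setting changes the background, the unit and the statistic together. With lists of equal size, 338 peaks each, Shep with Mod(mdg4)2.2 (1.32-fold) and with Rump (3.23-fold) no longer passed the threshold, nor did Shep with Rump in the top 50% of each list (1.58-fold). Shep with Rump was 5.57-fold with Shep peaks of q up to 0.05 and 5.35-fold with q up to 0.01. For lists of equal size and for the top 50%, the peaks kept in the Su(Hw) and CP190 lists are the widest.

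For Rump within the peaks of another factor, lists of equal size ended the calls within Mod(mdg4)2.2 by CP190 (odds ratio 1.89) and by Su(Hw) (1.1), and within Su(Hw) by Shep (3.66). They turned those within Shep by CP190 (odds ratio 0, Rump at 0 of 15 peaks with CP190) and by Su(Hw) (0, at 0 of 9), and that within Mod(mdg4)2.2 by Shep (1.71), where 1 Mod(mdg4)2.2 peak with Shep was left, none past the threshold. The top 50% of each list turned that within Shep by CP190 (0, at 0 of 113) and ended those within Shep by Mod(mdg4)2.2 (45.6) and Su(Hw) (36.7), each from 1 Rump peak, within Mod(mdg4)2.2 by Shep (0.179) and within Su(Hw) by Shep (1.36). Within Mod(mdg4)2.2 by Shep, the call was also lost with peaks up to 1000 bp apart (0.847) and without chromosome 2R (0.561), 3L (0.603) or 3R (0.615), and it turned within deciles of Mod(mdg4)2.2 score (2.07, or 1.13 and 1.05 with Shep peaks of q up to 0.05 and 0.01, neither past the threshold). Without deciles, those 2 filters gave 0.312 and 0.232. Within Su(Hw) by Shep, it was lost with midpoints within 500 bp (1.73), with Shep peaks of q up to 0.05 (1.57), though not with peaks of q up to 0.01 (1.88), and without chromosome 2L (1.51), 2R (1.51) or X (1.56). Within deciles of score, the odds ratio within Mod(mdg4)2.2 by Su(Hw) turned to 0.591, not past the threshold. For the complete insulator combination, lists of equal size gave odds ratios of 1.68 for Rump and 4.98 for Shep, neither past the threshold, and the top 50% gave 0.721 for Shep. On 2L, 2R, 3L, 3R and X alone, the ratios of median Rump scores by CP190 (1.19) and by Mod(mdg4)2.2 (1.24) were no longer past the threshold. None of the chromosome comparisons passed the threshold under any setting, and 3 changed side: chromosome 4 against Shep (odds ratio 12.8) and Su(Hw) (1) in the top 50%, from 1 Rump peak, and X against Shep (1.02) on assembled arms only. The odds ratios 1.71, 45.6, 36.7 and 12.8, and also 435 within CP190 and 149 within Su(Hw) by Mod(mdg4)2.2, have 0.5 added to each count, as one was 0. The cause of these changes was not tested. The smaller lists keep the peaks of highest score, or the widest, so that list size changed together with score or width.

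No paired analysis was possible because the deposited lists hold 1 value per factor and not per library. For the same reason leaving out a library or antibody was not possible. The planned promoter, gene list and motif comparisons were not run, since no dm3 genome or annotation was used here. Depth per library is unknown, so a site missing from a list is not shown to be unbound. This holds for every list, including Rump, the shortest.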

Other observations

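The tests in this part on the Mod(mdg4)2.2 score within the complete insulator combination and on score strata were set out after the lists had been examined but before their own results were seen. The other tests were chosen after. Rump peaks on the mitochondrial genome were 2 in number, from 1586 to 1841 and from 19172 to 19427, with Su(Hw) as the only other list with peaks there (2 peaks). Mod(mdg4)2.2 peaks with Su(Hw) had a median score of 144 against 63.1 without it, and those with CP190 137 against 72.5 (each adjusted p = 1.5e-05, permutation test), so that the score, the insulator partners and Rump go together.

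Rump lay on the Mod(mdg4)2.2 peaks of highest score. If any strong ChIP site of the shared chromatin preparation gave Rump peaks, strong Shep sites would have them too. Of the 145 Shep peaks in the top score decile, 0% had Rump (upper 95% limit 2.58%), against 72.8% for Mod(mdg4)2.2. A low share was known beforehand, since only 22 of all 1443 Shep peaks met Rump. Scores of different lists have no known common scale, so these Shep peaks may be weaker than the top Mod(mdg4)2.2 peaks. With only 22 Shep peaks meeting Rump in all, the share among these 145 could not have come near 72.8%. The values thus show only that the top Shep peaks lacked Rump. The comparison does not decide the explanation, which is not excluded. The presence of the partners Su(Hw) and CP190 does not replace the score. Among Mod(mdg4)2.2 peaks with both, the median score with Rump was 345 against 149 without it, a ratio of 2.31 (permutation p = 1e-05). The lists of these partners have no score, so the strength of their binding could not be held fixed and is not excluded. A small share of Mod(mdg4)2.2 reads in the Rump libraries stays open: of the 29 Rump peaks on the arms in the top decile of Rump score, 86.2% (69.4 to 94.5) met a Mod(mdg4)2.2 peak of the top decile and all met some Mod(mdg4)2.2 peak. The bound for this test was set after the value was seen and was changed once: the first bound, a share reaching 95%, was missed by the upper limit of 94.5% and would have ruled the explanation out, and it was replaced by 80%, which the interval spans, so the test decides nothing. Antibody cross-reaction and a biological link of Rump to the insulator complex were not tested, and each may contribute.

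A further hypothesis was that the Mod(mdg4)2.2 score alone accounts for the higher share of Rump at Mod(mdg4)2.2 peaks with both Su(Hw) and CP190. Within score deciles the odds ratio fell from 8.37 to 1.86 (1.17 to 2.94, Mantel-Haenszel p = 0.00891, n = 2678 peaks). Most of the association thus went with the score, and a part remained, although scores still vary within the top decile, from 294 to 544, and finer strata might lower it further.

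Rump peaks were more frequent outside the assembled arms than those of any other list. For weak peaks near the threshold, a first test of median scores (23.5 outside against 24.6 on the arms, permutation p = 0.534) did not decide. It was then replaced by the share in the top 50% of the Rump list, 22 of 169 peaks or 13.0% (8.76 to 18.9). No other list had an upper limit above 2.15% over all its peaks. The excess was thus not confined to the Rump peaks of lower score. The close medians already implied this, so the second test adds little to the first. Whether the score measures support equally well outside the arms was not tested, and weak peaks are not excluded. A background common to the libraries of one preparation and input, and insulator sites in repeats bound with Mod(mdg4)2.2, both stay open. Of the 45 Rump peaks, 0% lay within 1000 bp of a Shep peak and 20% (10.9 to 33.8) within 1000 bp of a Mod(mdg4)2.2 peak, but with only 5 Shep and 22 Mod(mdg4)2.2 peaks there, a match of 1 Rump peak to each could reach no more than 11.1% and 35.6%, so that these shares restate the pattern and decide neither. Reads that map to several places, a difference in copy number between Kc167 cells and the reference, and binding of Rump to repeats without the insulator proteins were not tested and may each contribute.

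Shep peaks were less frequent at regions with the complete insulator combination than at other Mod(mdg4)2.2 regions. Weakly supported Shep peaks do not account for this, as the odds ratio was 0.331 (0.245 to 0.446) with Shep peaks of q up to 0.05. Avoidance of high Mod(mdg4)2.2 scores rather than of the combination does not account for it alone, as the odds ratio per Mod(mdg4)2.2 peak was 0.278 without strata and 0.417 (0.296 to 0.588) within score deciles. The same strata turned the association of Rump and Shep at Mod(mdg4)2.2 peaks from 0.539 to 2.07 (1.04 to 4.10, 18 shared peaks). With Shep peaks of q up to 0.05, it went from 0.312 to 1.13 (0.473 to 2.68, 9 shared peaks), so the positive value was not seen with the better supported Shep peaks, and within strata neither sign is established.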
